A study of Mus musculus with 7 samples.

How the data were processed

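Chromatin immunoprecipitation with an antibody to acetylated lysine 27 of histone H3 (H3K27ac) was followed by sequencing in 7 mouse libraries. Per the labels' protocols, fixed and sonicated cell lysates were precipitated, the recovered DNA was copied by whole genome amplification, and single-end reads were taken on an Illumina instrument. Amplification before library preparation can copy some fragments more than others, and single-end reads give no fragment ends, so peak heights and widths carry that error. Reads were aligned with Bowtie 0.12.7 and handled with SAMtools 0.1.18 on the mm10 build, per the submitters' processing notes.

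For each library the authors deposited 1 list of peaks, called per library and not on pooled samples, with a chromosome, a start, an end, a peak name and a score. The peak names carry the prefix that the caller MACS writes, per the peak names in the files; its version, settings and control input were not given in the sources used here. The deposited score of a peak is the authors' value, has no stated unit, starts at about 50.0 in all 7 lists, and was used only to rank peaks within a list. The authors' start and end positions were used as deposited and are printed 1-based on mm10. Read counts and library sizes are not given by peak lists, so the read depth of each library is unknown and no counting interval was computed. The number of peaks is the nearest measure of yield, and it ranged from 12127 in GFP-positive replicate 2 to 35431 in GFP-negative replicate 1.

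Peaks on chromosomes 1 to 19 and X were kept. Because list length alone changes overlap, every list was reduced to its 12127 highest-scoring peaks, the length of the shortest list, with ties settled by width and then position. These are called the equal lists below, and the full lists are those the authors deposited. Peaks of the 6 mTEC libraries that overlapped by 1 bp or more were merged into regions, and a region was present in a library that had at least 1 bp of peak there. Overlap between a pair of libraries was the Jaccard index, the shared length over the joint length, with 10 circular rotations per pair for the chance level.

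Gene positions came from a table of RefSeq genes on GRCm38.p6, the assembly that mm10 names, with 21631 protein-coding genes on these chromosomes. The table gives no strand, exons or untranslated regions, so a transcription start could not be placed from it; the strand of Aire alone was taken from textbook knowledge. Distances that had been set from the start were therefore taken from either annotated gene end: a locus was the sequence within 25 kb of either end, and a peak was near a gene when it lay within 2 kb of either end. Neighbouring genes share such windows, so 1 peak can count for several loci. Whether a region falls in an exon or intron is not analysed here.

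Covered length, the bp of a locus under peaks of the equal lists, was compared between GFP-positive and GFP-negative mTEC libraries with limma 3.58.1 in R 4.3.3 and robust empirical Bayes. The scale was log2 of covered bp plus a pseudocount of 500, which understates differences at loci with little coverage. Libraries were centred on their median over loci covered in all 6, loci with a mean under 500 bp were left out, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In the fit all loci received nearly the same standard error, whatever their covered length. Limma-trend, which lets the error depend on the mean, was 1 of the alternatives. The 19 gene lists were tested with limma's camera at an inter-gene correlation of 0.01 and with an estimated correlation. Single values were compared by an exact two-sided permutation test of group means, which cannot go below p = 0.1 with 3 against 3. D10 has 1 library, so its comparison has no test.

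The limma script was tested on simulated data, made by permuting the values of 7830 loci. The GFP-positive values of 50 loci per fold size were raised to that multiple of the larger of the permuted value and the locus mean. GFP-negative values stayed as permuted, so the planted difference between the groups could be smaller or larger than the stated fold. Among loci covered in all 6 libraries the robust fit recovered 0% of those planted at 2-fold, 4% at 4-fold, 68% at 8-fold and 100% at 16-fold, with 4 false calls. On 20 permuted tables with no planted difference, limma-trend made 0.35 calls per table on average and at most 2, and the robust fit made 0. Each locus was permuted on its own, so loci that share peaks no longer moved together and differences between whole libraries were lost. These counts are therefore no false-call rate for the real data, where neighbouring loci can be called through the same peak. A test of the region script recovered 200 of 200 planted regions.

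The labels give replicates 1 to 3 in both mTEC groups, each from thymi pooled from 6 to 12 mice, and do not say that a number marks a shared pool or day. P-values of tests between libraries measure the spread between libraries, which holds the pools and their preparation. Fisher's exact test over regions does not measure that spread.

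The genes named were fixed by rule: Aire; the 10 loci per direction with the smallest p among those with all 3 libraries of 1 group beyond all 3 of the other; up to 4 members per gene list with the smallest p; the 5 widest regions found only in each GFP group; and the 10 loci per direction that differed most between D10 and mTEC. Where several loci shared the same peaks, the gene whose end lay nearest stood for them, and its own values are given. Some of the genes so chosen are not reported here. The lists covered mature mTEC, immature mTEC, thymic epithelial identity, cortical TEC, NF-kB pathway, Aire partner, cornified late mTEC, thymic tuft cell, peripheral tissue antigen, interferon response, cell cycle, T cell, Th2 cell, thymocyte, B cell, dendritic cell and macrophage, fibroblast, endothelial and housekeeping genes. All members but 1, Mx1, matched the gene table, Spt1 through its synonym. Tests, lists and most alternatives were fixed before the data were examined. The alternatives were the full lists, the top 6063 peaks of each library, other pseudocounts (100 and 2000 bp), windows (10 and 50 kb), centrings and filters, limma-trend, a replicate block, other merging rules, and each library left out in turn. Equal lists of the widest peaks were added after seeing the data, as were the comparison of the Aire peak's width and the test of how near group-only regions lie to genes. Per the labels, GFP-positive cells were sorted as MHC-II high and GFP-negative cells as MHC-II positive, so the groups differ in that gate too. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used. Peaks on chromosomes Y and M were left out of all comparisons.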

Results

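H3K27ac, a histone mark of active promoters and enhancers, was profiled in 7 libraries to look for sequence that controls Aire. Aire is the transcriptional regulator that lets medullary thymic epithelial cells (mTECs) express antigens of other tissues, to which developing T cells are made tolerant. The mTECs came from Adig mice, a reporter strain in which GFP marks cells with Aire expression, at 4 to 6 weeks of age. Live, CD45-negative, EpCAM-positive, Ly51-negative cells were sorted into a GFP-negative, MHC-II-positive fraction and a GFP-positive, MHC-II-high fraction, with 3 libraries each, so the groups differ in their MHC-II gate as well as in GFP. The control was 1 library of D10.G4.1, a Th2 helper T cell line from AKR/J mice. Each library is a list of peaks, and the read depth behind them is unknown.

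The GFP-negative lists held 35431, 27276 and 21139 peaks and the GFP-positive lists 23912, 12127 and 18671, with 12574 in D10. The means were 27949 ± 7170 and 18237 ± 5904 peaks (SD, n = 3 each; exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). The difference of -9712 peaks became -5970.8 without GFP-negative replicate 1. The lists covered 20.03 ± 3.90 Mb in GFP-negative and 13.9 ± 3.77 Mb in GFP-positive libraries (n = 3 each; exact permutation p = 0.2). In equal lists, 21.3% ± 0.992 of GFP-negative and 16.6% ± 2.24 of GFP-positive peaks lay within 2 kb of a gene end (n = 3 each; exact permutation p = 0.1), and in the full lists 19.4% ± 1.31 and 16.5% ± 1.89 (exact permutation p = 0.2). The value was 24.6% in D10 in both, and 5.62% of the genome lies that near.

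A peak over the 5' end of Aire was present in all 6 mTEC lists and absent from the D10 list. Aire lies on chromosome 10 from 78030022 to 78043610 (mm10) and is transcribed towards lower coordinates, so its 5' end is the higher one; this strand is textbook knowledge, not a value of the gene table, and what is called 5' or upstream here rests on it. In the GFP-positive libraries the peak ran from 78043226 to 78049709, from 78043540 to 78047825 and from 78043346 to 78049721, all of it inside the annotated span of Dnmt3l, a neighbouring DNA methyltransferase-like gene (78042287 to 78063622). It was 6484, 4286 and 6376 bp wide there, against 4038, 2035 and 2986 bp in the GFP-negative libraries. The means were 5715 ± 1239 and 3020 ± 1002 bp, a ratio of 1.89 (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). The peak reached 5475 ± 1091 bp upstream of the Aire 5' end in GFP-positive and 2871 ± 1191 bp in GFP-negative libraries (n = 3 each; exact permutation p = 0.1). It was the widest of all peaks in GFP-positive replicates 1 and 3 and ranked 3 in replicate 2, against ranks of 3, 184 and 17 in the GFP-negative libraries. A narrower peak between Pfkl and Aire, near 78018246 to 78018762 in GFP-positive replicate 1, overlapped peaks of 3 other mTEC libraries and none of D10; it was picked after its values were seen.

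**Figure D1:**
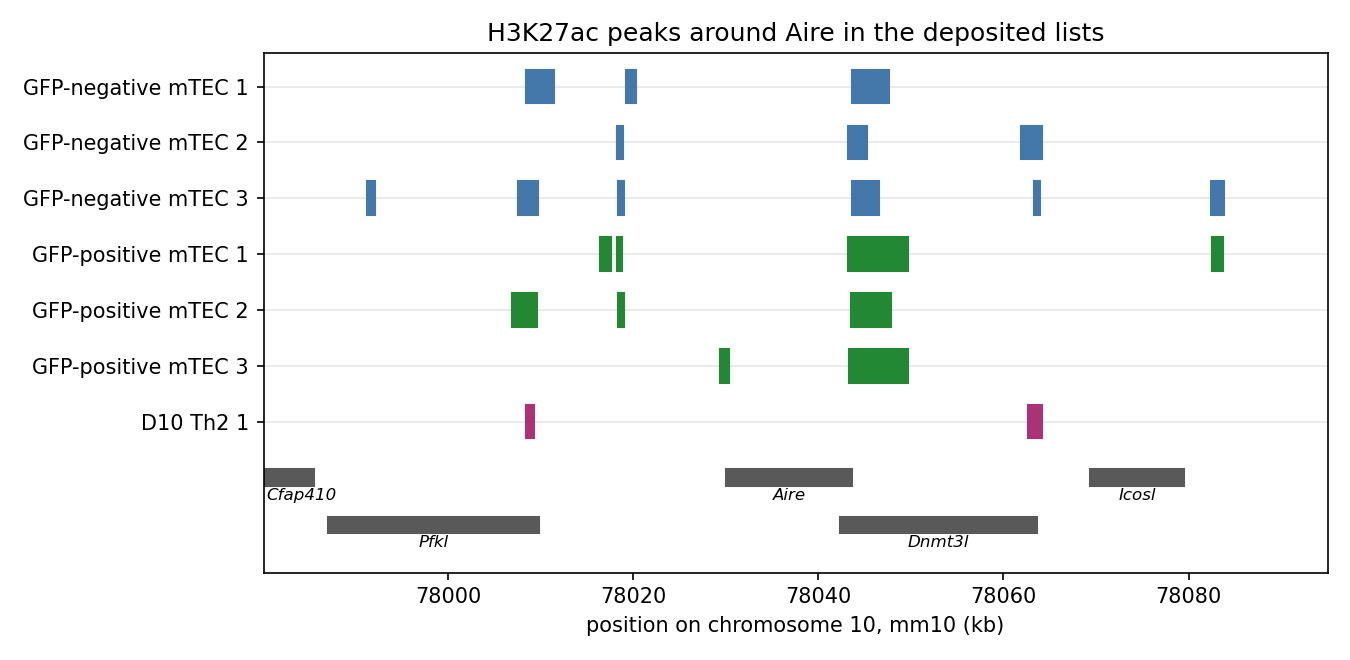
Peaks of the deposited lists around Aire on chromosome 10, with 1 row per library and coloured blocks for peaks; the horizontal axis is the mm10 position in kb, and grey bars are annotated protein-coding genes. A block over the 5' end of Aire is present in the 6 mTEC rows, absent in D10, and 6484, 4286 and 6376 bp wide in the GFP-positive rows.

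Over the whole locus, 25 kb to each side of the gene ends, equal lists covered 7417 ± 941 bp in GFP-positive and 3518 ± 628 bp in GFP-negative libraries, with 2319 bp in D10 (SD, n = 3 each; exact two-sided permutation p = 0.1). The equal list of GFP-negative replicate 2 did not hold its peak over the Aire 5' end, whose score of 57.91 was too low. In the full lists the values were 7719 ± 466 and 6437 ± 1539 bp (n = 3 each; exact permutation p = 0.3), a ratio of 1.20 against 2.11 in the equal lists. The log2 difference in covered length was 1.02 ± 0.70 (SE) in the robust limma fit, with a Benjamini-Hochberg adjusted p of 0.8352. With limma-trend it was 1.02 ± 0.17 with an adjusted p of 1.406e-05, the smallest of the 7830 loci. Limma-trend was run on the equal lists only, so its adjusted p carries the effect of these unequal lowest scores. By limma-trend the adjusted p was 0.1317 without GFP-positive replicate 1 and 0.23 without GFP-positive replicate 2, and at most 0.03005 without any other library.

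**Figure D2:**
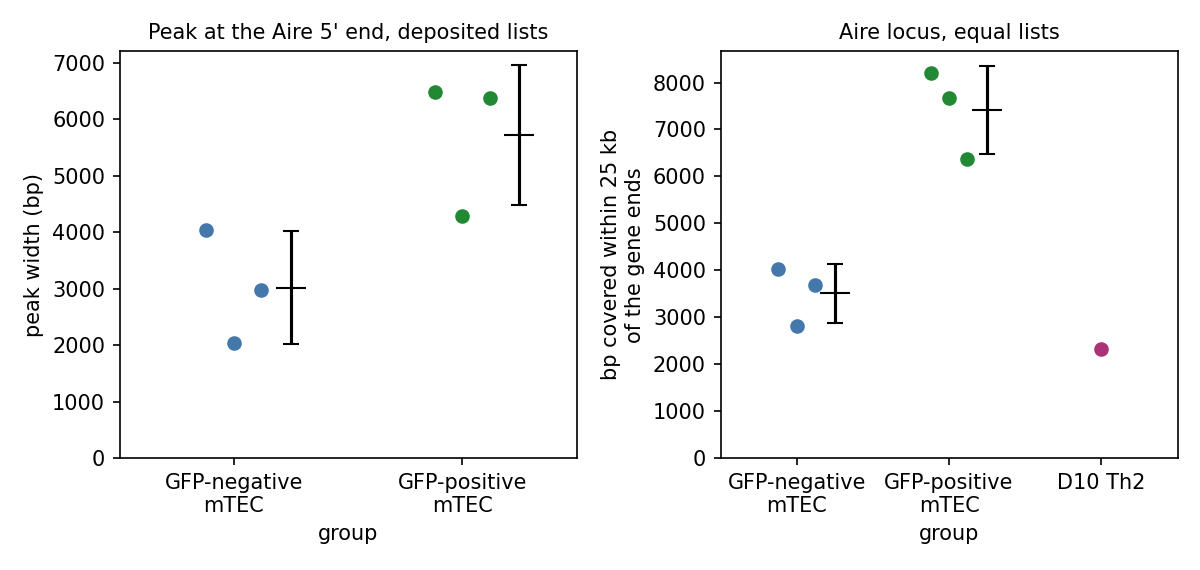
Left, width in bp of the peak over the Aire 5' end in the deposited lists; right, bp covered by peaks of the equal lists within 25 kb of the Aire gene ends. Points are libraries, and bars beside them are the mean and SD of 3; the GFP-positive widths (4286 to 6484 bp) all lie above the GFP-negative widths (2035 to 4038 bp).

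Across all gene loci, few or none passed a test between the GFP groups, depending on the fit. By the robust limma fit, 0 of 7830 loci had longer and 0 had shorter coverage in GFP-positive libraries at an adjusted p under 0.05, while 529 loci had an unadjusted p under 0.05 (227 longer, 302 shorter, 392 in all expected by chance). Limma-trend called 7 loci, all longer in GFP-positive libraries, and 534 at an unadjusted p under 0.05. Besides Aire these were Dnmt3l, whose window holds the same peak, a group of neighbours on chromosome 9 (Amigo3, Gmppb, Rnf123 and Ip6k1, an inositol phosphate kinase gene), and Wdr31. These were named after their values were seen, except Aire and Ip6k1. Wdr31 shares the peaks next to Bspry. The log2 difference was 0.85 ± 0.18 at Dnmt3l, 1.95 ± 0.47 at Ip6k1 and 2.54 ± 0.62 at Wdr31 (SE; limma-trend adjusted p = 0.01564, 0.04557 and 0.04557). The limma-trend count was 0 without GFP-positive replicate 1 or 2, 1 without GFP-negative replicate 1 or GFP-positive replicate 3, and 2 without GFP-negative replicate 3.

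Loci with more coverage in all 3 GFP-positive libraries included Kit, the stem cell factor receptor gene, and Syk, a gene for a tyrosine kinase of immune receptors. The Kit locus (chromosome 5, 75574987 to 75656722) had 2588 ± 1465 bp in GFP-positive and 0 bp in each GFP-negative library, and Syk had 1860 ± 690 bp against 0 bp (SD, n = 3). Values of 0 bp here and below are of the equal lists, which drop the lower-scoring peaks of longer lists. A full list could still hold a peak at such a locus. Inpp5b (chromosome 4, 124741827 to 124801511) had 2898 ± 1581 bp, Ubac1 2740 ± 1345 bp, Tspan14 2239 ± 1970 bp and Micos10 2420 ± 699 bp, all against 0 bp. Ip6k1 had 4110 ± 552 bp against 1046 ± 1210 bp, Bspry 3141 ± 932 bp against 651 ± 120 bp, Cmah 3704 ± 1525 bp against 922 ± 994 bp and Cmtm6 1808 ± 474 bp against 530 ± 498 bp. None of these 10 passed the robust limma test, and their adjusted p-values lay between 0.4379 and 0.7544.

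In the other direction, Kdm1a, which encodes a histone lysine demethylase, had 3029 ± 1331 bp in GFP-negative and 0 bp in each GFP-positive library (chromosome 4, 136550533 to 136602787; SD, n = 3). Ppp1r15b had 2812 ± 763 bp, H3f3a, a histone H3 variant gene, 2386 ± 1057 bp, Morc3 1804 ± 430 bp and the MHC class I gene H2-D1 1445 ± 538 bp, all against 0 bp. The tetraspanin gene Cd9 had 3089 ± 1707 bp against 174 ± 302 bp, Slc3a2 3170 ± 803 bp against 341 ± 591 bp, the catenin gene Ctnnd1 2630 ± 709 bp against 253 ± 438 bp, Proser2 2226 ± 426 bp against 154 ± 267 bp and Hp1bp3 1573 ± 253 bp against 741 ± 650 bp. None passed the robust limma test, with adjusted p-values from 0.4379 to 0.8567. Of the loci tested, 380 had all 3 GFP-positive values above all 3 GFP-negative values and 559 the reverse, where chance gives 5% each way if values are untied.

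Among the gene lists, mature mTEC and B cell genes had the smallest camera p-values, and neither passed. Counts of longer members in this and the next paragraphs go by the sign of the limma log2 difference, which for some genes is not that of the bp means. Of the 12 mature mTEC genes tested, 9 were longer in GFP-positive libraries, with Cd74, the invariant chain of MHC class II, at 2241 ± 1466 against 296 ± 513 bp, and Tnfrsf11a, the receptor RANK, at 4124 ± 1057 against 2392 ± 2460 bp (SD, n = 3). H2-Eb1, an MHC class II gene, had 2410 ± 2156 against 1068 ± 1849 bp. GFP-positive cells were also gated as MHC-II high. MHC class II genes did not all lean that way in the full lists, which differ in length. A peak within 2 kb of an end was in 3 GFP-negative and 1 GFP-positive libraries at H2-Aa and at Ciita. The counts were 3 and 2 at H2-Ab1, 1 and 1 at H2-Eb1, and 1 and 3 at Cd74. Aire itself is among the 12 tested genes of the list. The list did not pass camera (p = 0.02441, limma camera adjusted p = 0.2197; adjusted p = 0.7404 with an estimated correlation). Its adjusted p was 0.03574 with a pseudocount of 2000 bp and 0.04387 without GFP-positive replicate 2, in a range up to 0.7404 over all alternatives. With all 6 libraries and the pseudocount of 500 bp no list passed, and no member of any list passed over all loci by the robust limma fit. The median log2 difference of all tested loci was -0.08 in equal lists and -0.18 in the full lists.

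Immature mTEC genes had longer coverage in GFP-positive libraries for 1 of 7 members, with Ltbr, the lymphotoxin beta receptor gene, at 0 bp in each GFP-positive library and 1049 ± 918 bp in GFP-negative ones (camera adjusted p = 0.7066). The camera direction of this list was downward, and upward with the 10 kb window and without GFP-negative replicate 2 or GFP-positive replicate 2. Thymic epithelial identity genes were longer for 5 of 8 members, with Esrp1, an epithelial splicing regulator gene, at 1390 ± 350 against 747 ± 41.1 bp and Cldn3, a claudin gene, at 3430 ± 1423 against 4990 ± 1626 bp (adjusted p = 0.9075). Cortical TEC genes were longer for 2 of 5, with the thymoproteasome gene Psmb11 at 1189 ± 731 against 241 ± 417 bp (adjusted p = 0.9579); their median and mean log2 differences were -0.07 and -0.02 while camera gave an upward direction. Cornified late mTEC genes were longer for 2 of 6, with Krt80 at 162 ± 281 against 1494 ± 557 bp and Ovol1 at 817 ± 240 against 2346 ± 1219 bp (adjusted p = 0.5634). Thymic tuft cell genes were longer for 4 of 9, with the IL-25 receptor subunit gene Il17rb at 1861 ± 581 against 495 ± 857 bp (adjusted p = 0.8374); here the median was -0.07 and the mean 0.10. Peripheral tissue antigen genes were longer for 5 of 7, with Gad1 at 1263 ± 844 against 0 bp (adjusted p = 0.5634). In the full lists Gad1 had a peak within 2 kb of an end in 1 GFP-negative and 1 GFP-positive library.

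NF-kB pathway genes went both ways, 9 of 15 longer and 6 shorter in GFP-positive libraries (camera adjusted p = 0.5979). Nfkb2, the p100 subunit gene, had 0 bp in each GFP-positive library and 1404 ± 930 bp in GFP-negative ones, and Tnfaip2 had 350 ± 303 against 2127 ± 597 bp. Bcl3 had 1364 ± 1665 against 0 bp and Birc3 2723 ± 1572 against 887 ± 819 bp. In the full lists Bcl3 had a peak within 2 kb of an end in 1 GFP-negative and 0 GFP-positive libraries, and Nfkb2 in 2 and 0. Aire partner genes were longer for 6 of 14, with the deacetylase gene Sirt1 at 2019 ± 854 against 437 ± 756 bp (adjusted p = 0.8374). Interferon response genes were longer for 1 of 4 (Cxcl10, 350 ± 606 against 819 ± 277 bp; adjusted p = 0.8496), cell cycle genes for 4 of 6 (Pcna, 583 ± 525 against 1562 ± 417 bp; adjusted p = 0.9579), and housekeeping genes for 5 of 8 (Ppia, 1561 ± 877 against 614 ± 181 bp; adjusted p = 0.5634). Cell cycle genes had a median of 0.11 and a mean of -0.10.

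Markers of other cells were uneven. B cell genes were longer in GFP-positive libraries for 3 of 4 members (camera p = 0.01241, adjusted p = 0.2197; adjusted p = 0.7404 with an estimated correlation, and 0.03574 with a pseudocount of 2000 bp). Blk, a kinase gene, had 4318 ± 2315 against 998 ± 947 bp and Cd79a, a chain of the B cell receptor, 1630.0 ± 157 against 441 ± 390 bp. The member not counted as longer, Cd22, had a longer mean in GFP-positive libraries, 1630.0 ± 1776 against 1333.7 ± 400 bp, and a log2 difference of -0.17 ± 0.73 (SE). T cell genes were longer for 3 of 5 (Cd3e, 1142 ± 673 against 314 ± 544 bp), Th2 cell genes for 4 of 6 (Ccr8, 1376 ± 1561 against 494 ± 855 bp), thymocyte genes for 1 of 2 (Ptcra, 487 ± 844 against 1399 ± 531 bp) and dendritic cell and macrophage genes for 4 of 8 (Cd68, 936 ± 988 against 1850 ± 485 bp). Endothelial genes were longer for 2 of 3, with Tek, an angiopoietin receptor gene, at 1178 ± 412 against 0 bp, and the only fibroblast gene tested, too few for camera, was Pdgfrb, at 2016 ± 2481 against 1682 ± 1624 bp. Camera adjusted p-values were 0.5634 for T cell, Th2 cell and endothelial genes, 0.8496 for thymocyte and 0.9579 for dendritic cell and macrophage genes. Adjusted over the list alone, the limma fit left 1 B cell gene, Blk, and 1 endothelial gene, Tek, past the threshold, and 0 in the other lists.

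Some regions had a peak in all 3 libraries of 1 GFP group and none of the other. In the equal lists 138 were in GFP-positive and 193 in GFP-negative libraries only, out of 56658 merged regions. The 9 other splits of the 6 libraries, which mix the GFP groups, gave 161 to 203 such regions each against 331. A single mixed set, GFP-negative replicates 2 and 3 with GFP-positive replicate 1, had 136, close to the 138 of the GFP-positive libraries. Many regions can thus separate 3 libraries from 3 without a GFP difference, and no single region is shown to differ. In the full lists the counts were 130 and 621, and in the top 6063 peaks 59 and 102. With 1 library fewer to match, the GFP-positive-only count was 566, 612 and 595 without GFP-positive replicate 1, 2 and 3, and the GFP-negative-only count 795, 718 and 671 without GFP-negative replicate 1, 2 and 3 and 317 without GFP-positive replicate 1. The widest GFP-positive-only region lay inside Samd4, on chromosome 14 from 46952294 to 46955900, with 2935 ± 591 bp covered (SD, n = 3). The next 4 in width were next to Bspry (chromosome 4, 62474484 to 62478035; 2924 ± 562 bp), inside Stam2 (chromosome 2, 52730500 to 52733790; 2777 ± 270 bp), next to Cmah (chromosome 13, 24486299 to 24488870; 2145 ± 323 bp) and near Pkdcc (chromosome 17, 83196304 to 83199129; 2043 ± 722 bp). In the full lists, 1 GFP-negative library also had a peak in the regions at Samd4, Bspry and Pkdcc.

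The 5 widest of the 193 GFP-negative-only regions lay at the glycolytic gene Aldoa (chromosome 7, 126798156 to 126800866; 1961 ± 674 bp), inside Iqgap1 (chromosome 7, 80788546 to 80791092; 1884 ± 584 bp), at an end of Ppp1r15b (chromosome 1, 133129030 to 133131159; 1826 ± 266 bp), at an end of Proser2 (chromosome 2, 6096347 to 6098487; 1742 ± 567 bp) and inside Tnip1, an NF-kB pathway inhibitor gene (chromosome 11, 54935417 to 54937309; 1629 ± 216 bp). Gene ends were within 2 kb of 46.1% of GFP-negative-only and 15.2% of GFP-positive-only regions (odds ratio 4.77; Fisher's exact test over regions, two-sided p = 2.1e-09, which treats regions as independent). This p-value does not measure the spread between libraries. Sets of libraries that mix the GFP groups had shares from 13.95% to 46.62%. D10 also had a peak in 65 of the GFP-negative-only regions (33.7%), among them those at Aldoa and Tnip1, and in 35 of the GFP-positive-only regions (25.4%).

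**Figure D3:**
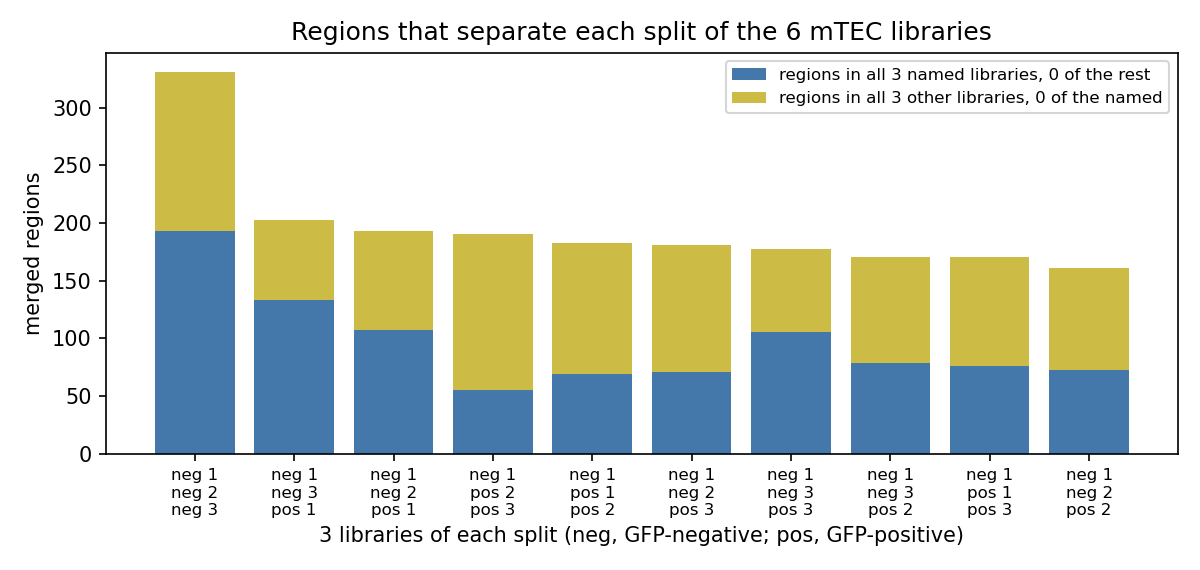
Number of merged regions that separate each of the 10 ways to split the 6 mTEC libraries into 3 and 3, with the named 3 libraries under each bar; the bar stacks regions found in all 3 named libraries and none of the rest (lower part) and the reverse (upper part). The split by GFP, at the left, has 331 regions, and the next has 203.

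Most regions were found in a single library. Of the merged regions, 81.9% had a peak in 1 mTEC library and 219 (0.39%) in all 6. Jaccard indices averaged 0.0898 within GFP-negative pairs, 0.0683 within GFP-positive pairs and 0.068 between the groups (3, 3 and 9 pairs), where rotated lists gave about 0.0018. Within-group pairs exceeded between-group pairs by 0.01098 on average, the most of the 10 splits of the 6 libraries. The difference was 0.00437 without GFP-negative replicate 1, 0.00548 without GFP-negative replicate 2, 0.00699 without GFP-negative replicate 3 and 0.0204 without GFP-positive replicate 1.

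Against D10 Th2 cells, mTEC libraries of equal lists had coverage that D10 lacked at Blnk, Pyroxd1 and Ptp4a2. D10 had coverage that the equal mTEC lists lacked at Il6, Plpp7 and Clnk. Of 21631 gene loci, 236 had coverage in all 6 mTEC libraries and none in D10 in equal lists, and 398 the reverse. The counts were 1020 and 132 in the full lists and 88 and 763 in the top 6063 peaks, and with 1 mTEC library fewer to match the first was 376 without GFP-positive replicate 2 and 372 without replicate 3. Among mTEC loci without D10 coverage, the adaptor gene Blnk had 3416 ± 912 bp, Pyroxd1 3719 ± 1117 bp, Ptp4a2 3664 ± 1659 bp, the thymus gene Tbata 2628 ± 1057 bp, the kinase gene Pim1 2522 ± 1219 bp, Fam167a 2684 ± 1458 bp, Gtf2i 2533 ± 1368 bp and Pfdn1 2230 ± 1197 bp (SD over 6 libraries). Relch, ranked through its neighbour Tnfrsf11a, had 1948 ± 1022 bp, and Il20rb, ranked through Nck1, had 2633 ± 912 bp against 919 bp in D10.

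In D10 the interleukin-6 gene Il6 led with 7467 bp against 0 bp in each mTEC library of equal lists, with a peak from 30006728 to 30011159 on chromosome 5. The cut to equal lists removed more peaks from most mTEC lists than from D10, whose full list held 12574. Full mTEC lists could thus have coverage at the loci named here, and which of them do is not reported. Plpp7 had 6076 bp, Clnk, a gene for an immune receptor adaptor, 5555 bp, Mup4 4762 bp, Babam2 4753 bp, Agfg1 4308 bp, Lipf 4208 bp, Ercc6l2 4097 bp, the odorant receptor gene Olfr1259 4077 bp and the intermediate filament gene Vim 3355 bp, all against 0 bp. In the top 6063 peaks D10 had no coverage at Il6, Mup4, Ercc6l2 or Vim. Of the Th2 cell members, Il1rl1, the IL-33 receptor gene, had 5461 bp in D10 and Ccr8 3275 bp, and of the T cell members Cd3e had 4216 bp. With 1 D10 library these differences have no test, and D10 comes from another mouse strain than the mTECs.

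Near gene ends, more mature mTEC genes had a peak in mTEC libraries than in D10, and the gap was smaller in equal lists. In the full lists, which differ in length, 1 of 16 mature mTEC genes had a peak within 2 kb of an end in D10 (6.25%), against 45.8% ± 13.0 in GFP-negative and 31.3% ± 18.8 in GFP-positive libraries (SD, n = 3), and 2 of 16 in GFP-positive replicate 2, the mTEC list nearest to D10 in length. In equal lists 1 gene had one in D10 and 2 to 4 in each mTEC library, or 16.67% ± 7.22 in GFP-negative and 16.67% ± 3.61 in GFP-positive libraries. Named after their values were seen, the 6 with such a peak in at least 4 mTEC libraries of the full lists were Aire, Cd40, Ciita, H2-Aa, H2-Ab1 and Cd74, and D10 had none of them; in equal lists 1 gene met that count. Thymic epithelial identity genes had 12.5% in D10 against 45.8% ± 13.0 and 27.1% ± 9.55 in the full lists, and 12.5% against 12.5% ± 6.25 and 18.75% ± 10.8 in equal lists. Immature mTEC genes had 7.14% in D10, 35.7% ± 7.14 in GFP-negative and 11.9% ± 4.12 in GFP-positive libraries (exact two-sided permutation p = 0.1 between the GFP groups), and 7.14% in D10 and 9.52% in both GFP groups in equal lists.

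Housekeeping and interferon response genes had more such peaks in D10 than in mTEC libraries of equal lists. In both kinds of list D10 had one for 8 of 16 housekeeping, 7 of 14 interferon response and 3 of 15 T cell genes. Housekeeping genes had 12.5% in each GFP-negative and 18.75% in each GFP-positive library of equal lists (n = 3 each; exact permutation p = 0.1), and 45.8% ± 20.1 and 29.2% ± 13.0 in the full lists (exact permutation p = 0.4), so the order of the GFP groups turned. Interferon response genes had 23.8% ± 14.9 in GFP-negative and 19.05% ± 4.12 in GFP-positive libraries of equal lists and 45.2% ± 8.25 and 28.6% ± 7.14 in the full lists, and T cell genes 8.89% ± 3.85 and 6.67% ± 0.0, then 15.6% ± 7.70 and 11.1% ± 3.85. For all protein-coding genes the shares in D10, GFP-negative and GFP-positive libraries were 15.97%, 13.9% ± 0.65 and 10.8% ± 1.47 in equal lists and 16.5%, 26.5% ± 4.41 and 15.95% ± 6.46 in the full lists.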

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

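Peaks on chromosome Y were outside all comparisons. The lists of GFP-negative replicates 2 and 3 and of GFP-positive replicate 3 each held 2 of them, above the 1 in the D10 list, and the other mTEC lists held 0 or 1. They lay at different positions, except for an overlap between 1285318 to 1286428 in GFP-negative replicate 2 and 1285797 to 1286578 in GFP-negative replicate 3. The sexes of the pooled mice are not given in the sources used here, and no explanation was tested.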

How the results depend on the processing

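Peak lists give neither reads nor depth, so no alternative could set a value against counting error. The limma-trend fits with a library left out or blocked, the equal lists of the widest peaks, the Aire peak width and its alternatives, the shared-region fits and the D10 counts with an mTEC library left out were chosen after seeing the data. The Aire locus, the Aire peak width, the Jaccard difference and the peak number kept their direction under all alternatives run, with library leave-outs from 3503.2 to 4419.2 bp, 2203.3 to 3410.3 bp, 0.00437 to 0.0204 and -13116.8 to -5970.8; the Aire locus difference was 1282 bp in the full lists and 1318 bp in the lists of widest peaks. Robust limma gave 0 longer and 0 shorter loci in every alternative, and limma-trend gave 7 longer; combined with leaving out a library it gave 1, 6 or 2 without GFP-negative replicate 1, 2 or 3, 0, 0 or 1 without GFP-positive replicate 1, 2 or 3, and 10 with the replicate block. Gene lists past the threshold numbered 2 with a pseudocount of 2000 bp (mature mTEC and B cell, adjusted p = 0.03574 each) and 0 to 1 with a library left out (mature mTEC, adjusted p from 0.04387 to 0.7227); the cause was not tested. Whether the replicate numbers pair the libraries is not known; same-numbered libraries did not deviate together (correlations of deviations -0.002, 0.016 and -0.011). With the replicate block robust limma gave 0 loci, 530 at an unadjusted p under 0.05, and 0 lists, and the Aire difference stayed 3898.7 bp.

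Region counts changed with list length, not all in the same direction. GFP-negative-only regions numbered 621 in the full lists and 102 in the top 6063 peaks, GFP-positive-only regions 130 and 59 (138 in equal lists), mTEC loci without D10 coverage 1020 and 88, and D10 loci without mTEC coverage 132 and 763. Leaving out a library relaxes the requirement by construction: GFP-positive-only regions then ranged from 175 to 612, GFP-negative-only regions from 261 to 795 and mTEC loci without D10 coverage from 328 to 376. Of 1490 values for single genes, 2 passed the threshold, Aire and Ip6k1 with limma-trend; the robust fit seldom reaches it, so the others say little, and changes of sign among them were not counted. Of 30 values for named regions, 16 kept the full separation. Of 60 values for D10 loci, 31 changed by less than the SD between mTEC libraries in equal lists. That SD was 0 at the loci higher in D10, so any change there counted as a move, and the count says little about them.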

Other observations

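The tests of the other splits of the libraries by the robust limma fit and the gene lists were chosen after their results were seen. So were the comparison of regions shared by all 6 libraries, the test of how near group-only regions lie to genes, the leave-outs under limma-trend and the width of the Aire peak. The splits for the Jaccard index and the group-only regions were planned beforehand, but what chance would give in them was written down after their results were seen. The model of Jaccard indices was chosen after the indices themselves, though not its result, had been seen.

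In equal lists D10 had a peak in 178 of the 219 regions found in all 6 mTEC libraries (81.3%). Peaks were not filtered for repeated sequence, and the highest-scoring places of every library, given at the end, are among these regions shared with D10. Among the regions without a D10 peak, 1 lay at Blnk (chromosome 19, 40992679 to 40996558; 2609 ± 581 bp covered, SD over 6 libraries) and others 17056 bp from the claudin gene Cldn3 (chromosome 5, 134965692 to 134969158; 2306 ± 721 bp), 24585 bp from Cd47 (chromosome 16, 49937088 to 49939434; 1536 ± 300 bp) and 16917 bp from the ephrin receptor gene Epha2 (chromosome 4, 141346301 to 141348391; 834 ± 287 bp). These 4 were picked after their values were seen, and whether such regions gather at any kind of gene was not tested.

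In the full lists 413 regions had a peak in all 6 libraries, and the one at Aire had the greatest mean covered length in GFP-positive libraries. By limma, 0 of the 413 differed in covered length between the GFP groups at an adjusted p under 0.05 and 35 had an unadjusted p under 0.05; the other splits gave at most 0 and 26. All 10 splits thus gave as many calls. In simulated data of 413 regions this fit recovered 15% of 2-fold and 100% of 4-fold differences, with 20 regions planted per fold and 3 false calls. The smallest adjusted p was 0.153, for a region inside Pfdn1 with 1069 ± 153 bp in GFP-positive and 2968 ± 736 bp in GFP-negative libraries (n = 3). The Aire region had a log2 difference of 0.93 ± 0.33 (SE), a limma p of 0.0195 and an adjusted p of 0.511.

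The peak over the Aire 5' end was wider in all 3 GFP-positive than in all 3 GFP-negative libraries. Of the 413 regions shared by all 6 libraries, 33 were separated in this way and 30 in reverse, with 20.6 expected each way by chance. A general widening of peaks in GFP-positive libraries would give the other shared regions a similar ratio, but their median log2 ratio of covered length was -0.005 (SD 0.411) against 0.92 at Aire, and 99.0% of them lay below Aire, with 4 at or above. Extra copies of Aire sequence in the reporter strain could raise signal at the locus in mTECs over D10, but both GFP groups come from that strain, so a comparison of mTECs with D10 does not bear on the wider peak in GFP-positive libraries. The flanks 10 to 100 kb away, relative to the genome mean, were covered 1.164 times as much in mTECs as in D10 (3.965), at 6.15, 5.909 and 0.0 times the genome mean in GFP-positive and 7.03, 3.257 and 5.355 in GFP-negative libraries. Whether extra copies add to the peak in mTECs stays open, because the extent of any added sequence is not given in the sources used here. A link with Aire expression, which the GFP sort stands for, may account for the wider peak and stays a hypothesis, since the higher MHC-II gate of the GFP-positive sort, and any unrecorded difference between the sorts, are confounded with it.

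The total number of group-only regions was larger for the GFP split than for any other, with 193 GFP-negative-only regions. The 138 GFP-positive-only regions were close to the 136 of a mixed set, GFP-negative replicates 2 and 3 with GFP-positive replicate 1. Better signal in the GFP-negative libraries would leave no similarity within groups if it acted as 1 factor per library. A model of log2 Jaccard indices with a term per library kept a same-group term of 0.214, and 0.191 to 0.255 with any library left out. Its highest value in the other splits was 0.0024, but the terms of the splits balance out by construction, so a high term in the GFP split lowers the rest. The model cannot decide against better signal that acts in another way. Jaccard indices averaged 0.0683 within GFP-positive pairs and 0.068 between the groups, against 0.0898 within GFP-negative pairs. A difference in H3K27ac that goes with GFP or with the MHC-II gate, which cannot be separated here, is a candidate explanation, and preparation of the fractions on separate occasions, which the labels do not record, stays open. The mean share of regions near a gene end was 46.1%, 35.0%, 24.97% and 15.2% for regions in exactly 3 libraries of which 3, 2, 1 and 0 were GFP-negative, but single sets of 3 libraries overlapped widely, from 23.29% to 46.62% with 2 GFP-negative libraries and from 13.95% to 34.78% with 1.

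With 10 splits, no share can be under 0.05: the real split gave 331 regions against 203 for the next, a Jaccard difference of 0.01098 against 0.00092, 7 loci by limma-trend against 0, 0 loci by robust limma against 0 (529 against 397 at an unadjusted p under 0.05), and 0 gene lists against 1. In each of the first 3 of these, 1 of 10 splits, the real one, reached the real value. In the last 2, 10 of 10 did. The Jaccard differences of the 10 splits balance out by construction, so the other splits are no independent chance level for the real one.

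High-scoring peaks were at first taken to be rarely shared, which raised the possibility of tall, narrow peaks from amplified or repeated reads. That premise did not hold: the top score quartile was found in another library more often (49.7% to 70.7%) than the lowest (27.1% to 44.4%). Peaks both in the top score quartile and in the lowest width quartile were shared less often than low-scoring wide ones in 6 of 7 libraries, with D10 the exception (64.7% against 48.1%), so the test did not decide, and no biological explanation was tested. The 3 highest-scoring peaks of every library, D10 included, lay at the same 3 places, from about 98666039 to 98667506 on chromosome 2, 35305014 to 35305827 on chromosome 9 and 19415508 to 19419859 on chromosome 14 in GFP-negative replicate 1.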
